A study of Mus musculus with 16 samples.

How the data were processed

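Gene expression was measured in mouse plasmablasts on Illumina whole-genome bead arrays. Per the labels, splenic B cells isolated with CD43 microbeads were stimulated in culture with lipopolysaccharide (LPS), a bacterial product that drives B cells towards antibody secretion, and plasmablasts were sorted as cells with low CD19 and positive CD138. The labels named 4 genotypes: Ctrl, Myc, IKK2 and Myc.IKK2. IKK2 is the kinase, encoded by Ikbkb, that activates NF-kB, and MYC is a transcription factor of growth and metabolism. The labels did not say how the added alleles were built or which part of each transcript they carry.

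The 16 deposited files came from 8 arrays on 2 chips, here called S1 and S2 after the sample titles, with each genotype once per chip and 2 files per array. The 2 files of an array were read as separate strips of the same hybridised array, which the labels do not state, and the titles number them as they would replicates. Files of the same array correlated at r = 0.996 to 0.997 across probes, while arrays of a genotype on different chips correlated at r = 0.993 to 0.994. The median squared difference over the bead noise was 1.30 to 1.70 between files of an array and 2.53 to 2.92 between chips. No genotype had separate arrays on the same chip, so these values cannot tell strips of an array from separate samples on a chip. By the reading above, the files of an array were averaged and counted as 1 sample, which left n = 2 arrays per genotype. Nothing in the labels says that the arrays of a genotype came from separate animals or cultures. Xist, a transcript of the inactive X chromosome, averaged 7.76 on S1 and 12.35 on S2 in IKK2, and 7.83 and 12.15 in Myc.IKK2. A Y-linked gene went the opposite way. The arrays of each of these genotypes thus came from animals of different sex, which argues against a purely technical spread between them. For Ctrl and Myc the spread may be technical. P-values measured only the spread between these arrays.

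The main values were the authors' table of log2 expression values, as deposited. It was made in R 3.4 with lumi, per the submitters' processing notes, and the transform, background step and normalization were not given in the sources used here. The table held 45281 probes, and the median of each column was 7.94. Its upper end followed the log2 scanner intensity, with a 99th percentile of 14.75 against 14.79. Its lower end was compressed, with a median of 7.94 against 7.18 and a 5th percentile of 7.68 against 6.58, so changes of dim probes are understated. The base of the logarithm was read from this match, and centring by gene was absent. The deposited scanner files gave the intensity of single beads, per the file headers, with some values below 0, so a background had been subtracted before deposit. They held 46547 bead types per file, 987294 to 1036301 beads per file and a median of 21 to 22 beads per bead type. Beads over 3 median absolute deviations from the median of their type and beads not above 0 were removed, which together took 1.30% to 1.82% of beads. The median intensity per file was then 134 to 157. The number of arrays limits the precision.

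Bead codes could not be paired with gene names in the sources used here. By a provision fixed before the data were examined, the authors' table therefore served as the main source, and the scanner files served for checks. The platform annotation gave 1 gene symbol for 34885 probes and several for 18, and 10378 probes were unnamed here. Of the named probes, 34807 were matched by gene number to the mouse gene table, and no symbol changed (0 updated). The probes covered 19057 genes. Each gene was represented by the probe with the highest mean over all arrays, after removal of probes not above the array median on at least 2 of the 8 arrays. This left 12447 genes. Other probes of a gene that moved the opposite way are stated where a gene is named, unless that probe lay near background. No genome was used here, so positions of genes and probes are not reported. No column of per-sample values was left out (0 columns).

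All 8 arrays entered 1 linear model of the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called at an adjusted p under 0.05. The 6 comparisons were Myc, IKK2 and Myc.IKK2 against Ctrl, Myc.IKK2 against Myc, Myc.IKK2 against IKK2, and the interaction, which is the change from Myc to Myc.IKK2 minus that from Ctrl to IKK2. The median standard error (SE) of a log2 change was 0.0998, and 0.141 for the interaction. Gene lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01 between genes. They were tested again with an estimated correlation and with fry. The estimated setting also weakened lists whose estimate lay below 0.01. In Myc against Ctrl the IL6-JAK-STAT3 list (named below) had an estimate of -0.028, and its unadjusted camera p went from 6.38e-05 to 0.0115. A call lost in this setting thus does not show that list members moved together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0 served the random block.

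The model was tested on simulated data with altered genes placed among 12447. For Myc against Ctrl it recovered 46.3% of log2 changes of 0.5, 91.0% of changes of 1 and 98.5% of changes of 2. For IKK2 and Myc.IKK2 against Ctrl these shares were each 49.3%, 92.5% and 100%. False calls made up 3.68%, 6.40% and 4.17% of calls in the 3 comparisons. Each comparison was simulated once, with 66 or 67 genes per size of change, so the shares do not tell the comparisons apart. The noise was independent between genes and arrays, with no sex pattern and no difference shared within a chip. Far fewer genes were altered than were called in the real data. The false share of the real calls is therefore not known from the simulation.

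The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, except where stated. By that rule, Myc and Ikbkb were given on each array. Against Ctrl, the 10 largest rises and the 10 largest falls were taken among called genes that moved the same way on both chips, and 5 of each in the other comparisons, passing over symbols that are only clone or model names. From each list up to 4 members with the smallest p were taken, and Il6, Il6ra, Il6st, Stat3, Socs3, Prdm1, Xbp1, Irf4 and Sdc1 were taken in each comparison with Ctrl. The 20 lists were targeted genes, NF-kB target genes, the IL6-JAK-STAT3 pathway, ribosome biogenesis, MYC-linked metabolism, cell cycle, CDK inhibitors and p53 targets, the plasma cell programme, the mature B cell programme, the unfolded protein response and secretion, survival and apoptosis regulators, cytokines, chemokines and receptors, immunoglobulin genes, the interferon response, immediate early and heat shock genes, T cell, NK cell, myeloid and dendritic cell, and erythroid and platelet markers, and sex-linked genes. Of these, 17 were tested as sets. Some lists share members, such as Bcl2l1, Cflar and Fas in the NF-kB and survival lists and Ccl5 in the NF-kB and cytokine lists. Results of such lists are therefore not separate findings.

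The alternatives fixed beforehand were no filter and a stricter filter on dim probes, the mean of all probes of a gene, the 16 files as separate samples with and without the array as a random block, the chip as a replicate block, eBayes with trend and robust settings, a fit of only the groups compared, and leaving out each array in turn. Other alternatives were chosen after seeing the data. They were a scanner scale, in which each file's scanner intensities were put back on the ranks of the table and then quantile normalised, scaled to the 75th percentile or corrected with normexp (offset 50), sex as a covariate, and a fit without the 2 arrays of male pattern. A background level of 7.97, was also chosen after seeing the data. It is the highest value, on arrays of the other sex, of the 4 Xist probes and 1 Y-linked probe that ranged over more than 2 log2. A Y-linked probe that did not differ with sex was left out and reached 8.02, so values near 8 may also be background. Each chip held all genotypes, so changes are also given within each chip. The chips are balanced over the genotypes, so the chip as a block left each log2 change the same and altered only its error.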

Results

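Transcript levels were compared in plasmablasts, the dividing antibody-secreting stage of B cells, from mice of 4 genotypes. The labels named them Ctrl, Myc, IKK2 and Myc.IKK2, and each had n = 2 arrays, 1 on each of 2 chips (S1 and S2). The series title concerns joint activation of NF-kB and MYC and dependence on the cytokine IL6, so the comparisons set each genotype against Ctrl and the joint genotype against each of the others. Values are on the log2 scale of the authors' table, and changes are differences of group means with the SE of the model. The number of arrays limits the precision.

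The first principal component of the 12447 genes tested held 55.3% of the variance. It placed the Ctrl arrays lowest, at -26.8 and -27.5, and the Myc.IKK2 arrays highest, at 24.7 and 21.2. The IKK2 arrays (-2.08 and -5.12) and the Myc arrays (7.20 and 8.44) lay between them. The next component, with 20% of the variance, parted Myc (13.3 and 16.4) from IKK2 (-17.0 and -13.6).

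**Figure D1:**
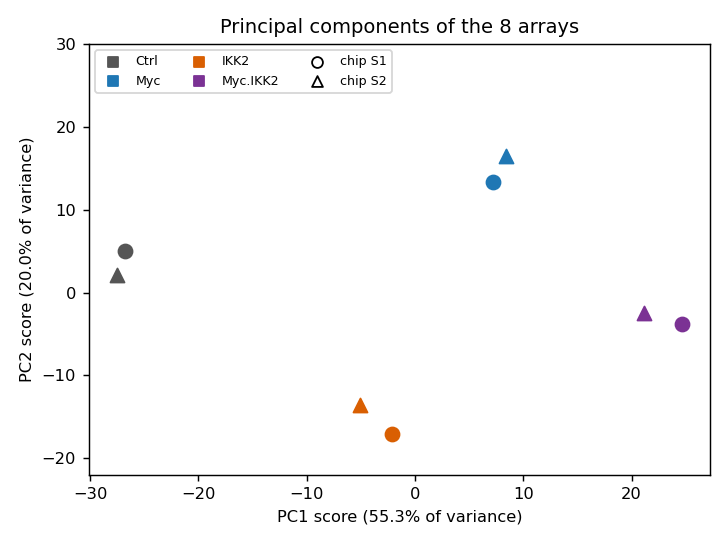
Scores of the 8 arrays on the first and next principal components of the 12447 genes tested (axes: PC scores, with 55.3% and 20% of the variance). Each point is an array, colour gives the genotype and shape the chip; arrays of a genotype lie side by side, with Ctrl at -26.8 and -27.5 and Myc.IKK2 at 24.7 and 21.2 on the first component.

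The targeted genes were read first. The brighter Myc probe measured 8.57 and 8.86 on the Ctrl arrays (S1 and S2), 7.99 and 8.0 on the arrays labelled Myc, 9.32 and 9.09 on those labelled IKK2, and 8.14 and 7.96 on those labelled Myc.IKK2. It fell by 0.72 in Myc against Ctrl (SE 0.12, adjusted p = 0.00402) and by 0.66 in Myc.IKK2 against Ctrl (SE 0.12, adjusted p = 0.00329). It rose by 0.49 in IKK2 against Ctrl (SE 0.12, adjusted p = 0.0321), a call that was lost without array S1 of Ctrl (0.35) or of IKK2 (0.37), without both arrays of male pattern (0.37), with sex as a covariate and with only these groups in the fit. On the Myc arrays and on array S2 of Myc.IKK2 the probe lay at about the background level of 7.97, so the size of its falls is uncertain, with ranges over the alternatives of -1.30 to -0.58 in Myc and -1.18 to -0.43 in Myc.IKK2 against Ctrl. The Ikbkb probe lay between 9.69 and 10.04 on all arrays, and its change passed the test in no comparison, with values of 0.12 in Myc, 0.02 in IKK2 and -0.07 in Myc.IKK2 against Ctrl. Where these probes lie relative to the added alleles is unknown here, so neither probe checks the labels, and the direction of the Myc probe went against the name of the genotype. All directions below are those of arrays labelled with each genotype. The Il6 probe lay between 7.78 and 7.96 on all arrays, not above the background level, and was not tested.

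The arrays also differed in sex-linked genes. Xist, the transcript of the inactive X chromosome, averaged 7.76 on array S1 of IKK2 and 7.83 on array S1 of Myc.IKK2, and the Y-linked gene Eif2s3y measured 11.2 and 10.9 there. On the other 6 arrays Xist averaged 12.2 to 13.1 and Eif2s3y 7.69 to 7.79. On chip S2 all arrays thus had the female pattern, and on chip S1 both genotypes with IKK2 had the male pattern.

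In arrays labelled Myc, 29 of 33 ribosome biogenesis genes rose against Ctrl, and 16 of 25 interferon response genes fell. Cd3eap, a subunit of RNA polymerase I, rose by 2.08 (SE 0.10, adjusted p = 1.84e-05), and the nucleolar genes Mybbp1a (1.91, SE 0.15) and Rrp1b (1.89, SE 0.16) rose as well. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 2.199 (SE 0.11, adjusted p = 3.58e-05, with 1.12 to 2.85 over the alternatives), and the mitochondrial ATPase gene Atad3a rose by 2.00 (SE 0.09). Isg15, a ubiquitin-like protein induced by interferon, fell by 2.27 (SE 0.25, adjusted p = 0.000575), and the kinase gene Sgk1 fell by 2.17 (SE 0.12). The transcription factor genes Egr3 and Egr2 fell by 2.17 (SE 0.31) and 2.11 (SE 0.32), and Egr3 ranged from -2.87 to -1.03 over the alternatives.

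Further large rises were Tmem41a (1.98), Thop1 (1.91), Pip4p1 (1.88), the deoxycytidylate deaminase gene Dctd (1.88) and the purine synthesis gene Atic (1.86). Another bright probe of Pip4p1 changed by -0.29. Further large falls were the activation marker Cd69 (-2.00), Usp18 (-1.83), the inhibitory receptor gene Ctla4 (-1.83) and Vpreb3 (-1.80). Speer3 (-1.74, SE 0.40) and Speer1 (-1.73, SE 0.41), members of a family of near-identical genes, completed the falls and are uncertain: both calls were lost without array S1 (-1.61 for Speer3 and -1.58 for Speer1) or S2 (-1.86 and -1.87) of Ctrl and without array S2 of Myc (-1.30 and -1.36), and with trend and robust settings. Over the alternatives Pip4p1 ranged from 0.80 to 2.06, Atic from 1.07 to 2.19 and Cd69 from -2.42 to -1.14.

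Of 33 measured ribosome biogenesis genes, 29 rose and none fell (30 and 0 adjusted over the list alone), with a median of 0.99 and within-chip medians of 1.02 on S1 and 0.98 on S2. Examples were the ribosomal RNA processing genes Nop2 (1.55) and Rrp12 (1.64) and the polymerase I gene Polr1b (1.68). Camera gave an adjusted p of 1.47e-23, and 0.0384 with an estimated correlation. Of 26 genes of MYC-linked metabolism, 18 rose and 3 fell (18 and 3 adjusted over the list alone), among them the purine gene Gart (1.58) and the transferrin receptor gene Tfrc (1.64). That list's adjusted p was 7.03e-09, and 0.055 with an estimated correlation. Of 32 cell cycle genes, 7 rose and 25 did not pass (9 rose adjusted over the list alone), with Cdk4 at 0.81 and Mcm2 at 0.57. The adjusted p was 3.76e-05, and 0.195 with an estimated correlation.

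Of 37 NF-kB target genes, none rose and 15 fell in arrays labelled Myc (0 and 17 adjusted over the list alone), with a median of -0.34 and within-chip medians of -0.40 and -0.21. Nfkbiz, an IkB family gene, changed by -1.27, the cytokine subunit gene Ebi3 by -1.12, Cflar, which blocks death receptor signalling, by -0.94, and Traf1 by -0.72. Camera gave an adjusted p of 6.94e-08, and 0.0794 with an estimated correlation. Of 23 IL6-JAK-STAT3 genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone), with the kinase gene Pim1 at -1.36 (-1.52 to -0.65 over the alternatives), the cytokine gene Il10 at -1.16 and the feedback inhibitor gene Cish at -0.84. As a set it had an adjusted p of 9.86e-05, and 0.055 with an estimated correlation. Il6ra (-0.22), Il6st (-0.41), Stat3 (-0.27) and Socs3 (-0.55) did not pass, with adjusted p-values of 0.362, 0.0627, 0.242 and 0.152.

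Of 25 interferon response genes, 16 fell and none rose in arrays labelled Myc (16 and 1 adjusted over the list alone), among them Trim30a (-1.41) and Irf9 (-0.90). For this list the adjusted p was 1.57e-08, and 0.0882 with an estimated correlation. Of 33 mature B cell genes, 14 fell and none rose (15 and 0 adjusted over the list alone), among them the chemokine receptor gene Cxcr5 (-1.34) and the complement regulator gene Cd55 (-1.10). Its set test gave an adjusted p of 8.78e-06, and 0.0882 with an estimated correlation. Of 28 plasma cell genes, 14 fell and 2 rose (15 and 2 adjusted over the list alone), with Slamf7 at -0.78 and the secretory pathway gene Fkbp11 at 0.63. The adjusted p was 4.1e-06, and 0.105 with an estimated correlation. Prdm1, the transcription factor gene of plasma cell differentiation, fell by 0.62 (SE 0.14, adjusted p = 0.017), a call that was lost without array S2 of Ctrl (-0.42) or of Myc (-0.50), with a range of -0.92 to -0.31 over the alternatives. Xbp1 (-0.03, near the top of the scale at 15.99 in Ctrl), Irf4 (-0.13) and Sdc1 (-0.04) did not pass. Sdc1 encodes CD138, by which the cells were sorted, so its level in each genotype may reflect the sort.

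Of 34 cytokine, chemokine and receptor genes, 11 fell and none rose in arrays labelled Myc (12 and 0 adjusted over the list alone), with the IL2 receptor gene Il2ra at -1.67 (adjusted p = 1.94e-05, and 0.055 with an estimated correlation). Of 37 genes of the unfolded protein response and secretion, 7 fell and none rose (7 and 0 adjusted over the list alone), with Ero1b at -1.03 and the chaperone gene Dnajb9 at -0.94 (adjusted p = 7.34e-05, and 0.0882 with an estimated correlation). Of 24 survival and apoptosis regulators, 10 fell and 1 rose (12 and 1 adjusted over the list alone), with Bcl2l1 at -0.77 and Bcl2l11 at -0.67 (adjusted p = 7.34e-05, and 0.0789 with an estimated correlation). Of 22 CDK inhibitor and p53 target genes, 9 fell and 1 rose (12 and 2 adjusted over the list alone), with Gadd45a at -1.23 and Cdkn2a at 1.01, with 0.66 to 1.19 over the alternatives (adjusted p = 0.00102, and 0.0695 with an estimated correlation). Of 22 immediate early and heat shock genes, 9 fell and 5 rose (11 and 5 adjusted over the list alone), with Dusp1 at -1.72 and the chaperone gene Hspd1 at 1.51 (adjusted p = 0.00448, and 0.224 with an estimated correlation).

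In all, 2495 of 12447 genes were called in Myc against Ctrl by limma, 1371 higher and 1124 lower (54.9% higher). Of them, 250 changed at least 2-fold (154 higher, 96 lower). With 75th percentile scaling on the scanner scale 2188 genes were called, 59.7% of them higher. All 2495 moved the same way on both chips, but they were called on these same arrays, so this is not replication. The chip as a block gave 2827 calls. Without array S2 of Ctrl 1516 genes were called, and without array S2 of Myc 1415.

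In arrays labelled IKK2, 19 of 33 ribosome biogenesis genes rose against Ctrl, 22 of 33 mature B cell genes fell, and of 37 NF-kB target genes 9 rose and 3 fell. Serpina3f, a serine protease inhibitor gene, rose by 2.98 (SE 0.24, adjusted p = 0.00035), the transferrin receptor gene Tfrc by 1.72 (SE 0.11, adjusted p = 0.000283), the NF-kB subunit gene Relb by 1.44 (SE 0.09, adjusted p = 0.000283) and the thymidine kinase gene Tk1 by 1.43 (SE 0.14). H2-Ab1, an MHC class II chain, fell by 1.20 (SE 0.08, adjusted p = 0.000283). Apoe, a lipid carrier protein, fell by 2.22 (SE 0.14), Sgk1 by 2.21 (SE 0.12) and the transcription factor gene Klf2 by 2.06 (SE 0.25). On chip S2, where all arrays had the female pattern, Serpina3f changed by 3.13, Relb by 1.56, Tfrc by 1.86, H2-Ab1 by -1.23 and Apoe by -2.09, and on chip S1 these values were 2.83, 1.32, 1.58, -1.18 and -2.36.

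The other large rises were Ccdc17 (1.74), the receptor kinase gene Axl (1.66, with 0.82 to 1.81 over the alternatives), Gstt1 (1.41), the amino acid oxidase gene Il4i1 (1.41), Cavin3 (1.38) and Ddt (1.36). The other large falls were Pinlyp (-2.33), Rsph1 (-2.16), the glutathione peroxidase gene Gpx3 (-2.04), Tmem52 (-2.01), Gh (-1.97), Gadd45g (-1.87) and Egr3 (-1.79). The call of Egr3 was lost without array S1 of IKK2 (-1.75), which is an array of male pattern, and its range over the alternatives was -2.41 to -0.91.

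Of 37 NF-kB target genes, 9 rose and 3 fell in arrays labelled IKK2 (12 and 5 adjusted over the list alone). Beside Relb, Nfkbie (0.94) and Tnip1 (0.86), which encode inhibitors of the pathway, rose, while Nfkbiz (-1.28) and the chemokine gene Ccl5 (-1.30) fell. As a set the list did not pass, with a median of 0.17, within-chip medians of 0.16 on S1 and 0.08 on S2, and an adjusted p of 0.0649 (0.522 with an estimated correlation). It passed in 8 alternatives, with adjusted p-values of 0.0064 with sex as a covariate, 0.0116 and 0.0468 with 75th percentile scaling and quantile normalization on the scanner scale, 0.015 without the 2 arrays of male pattern, 0.0166 without S1 of IKK2, 0.0292 without S2 of Ctrl, 0.0392 with no filter and 0.0418 with the chip as a block. Of 23 IL6-JAK-STAT3 genes, 4 rose and 5 fell (6 and 6 adjusted over the list alone), and the set test gave an adjusted p of 0.964, with a median of 0.04, a mean of -0.04 and within-chip medians of 0.13 and -0.11. Socs3, the feedback inhibitor of IL6 signalling, changed by -1.21 (SE 0.24, adjusted p = 0.0124). This call was lost without array S1 (-1.25) or S2 (-1.17) of Ctrl and without array S2 of IKK2 (-1.08). The calls of Il6ra (-0.55, adjusted p = 0.0385) and Stat3 (-0.55, adjusted p = 0.0336) were also lost without single arrays, Il6ra without S1 of Ctrl (-0.31), S1 of IKK2 (-0.53) or S2 of IKK2 (-0.57), and Stat3 without any Ctrl or IKK2 array (-0.59, -0.52, -0.59 and -0.51). Both calls were also lost with normexp, with no filter and with the mean of all probes, and that of Il6ra with only these groups in the fit, with sex as a covariate and without the 2 arrays of male pattern. Over the alternatives Il6ra ranged from -0.80 to -0.29 and Stat3 from -0.69 to -0.23. Another bright probe of Stat3 changed by 0.01. Il6st (-0.34), Prdm1 (-0.41), Xbp1 (0.02), Irf4 (-0.09) and Sdc1 (0.17) did not pass.

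Of 33 ribosome biogenesis genes, 19 rose and none fell in arrays labelled IKK2 (26 and 0 adjusted over the list alone), with a median of 0.50 and within-chip medians of 0.54 and 0.49. Nop2 (0.98), Nhp2 (0.95) and Rrp12 (0.95) were among them. Camera gave an adjusted p of 4.85e-15, and 0.0464 with an estimated correlation. Of 26 genes of MYC-linked metabolism, 15 rose and 1 fell (16 and 3 adjusted over the list alone), with Shmt1 at 1.09 and the serine synthesis gene Psat1 at 0.96. As a set it had an adjusted p of 1.04e-06, and 0.13 with an estimated correlation. Of 32 cell cycle genes, 14 rose and none fell (18 and 0 adjusted over the list alone), with the thymidylate synthase gene Tyms at 1.02 (0.47 to 1.21 over the alternatives) and Mcm3 at 0.74. For this list the adjusted p was 3.4e-09, and 0.236 with an estimated correlation.

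Of 33 mature B cell genes, 22 fell and none rose in arrays labelled IKK2 (24 and 0 adjusted over the list alone), with a median of -0.59 and within-chip medians of -0.52 and -0.77. Beside H2-Ab1, H2-Ob (-1.52), H2-Eb1 (-1.29) and the inhibitory receptor gene Cd22 (-1.50, with -2.12 to -0.86 over the alternatives) fell. Its set test gave an adjusted p of 1.21e-19, and 0.0464 with an estimated correlation. Of 25 interferon response genes, 9 fell and 1 rose (14 and 1 adjusted over the list alone), with Usp18 at -0.89 and Dhx58 at -0.77. The adjusted p was 2.85e-06, and 0.291 with an estimated correlation. Of 28 plasma cell genes, 5 fell and 2 rose (5 and 2 adjusted over the list alone), and the set test gave an adjusted p of 0.112.

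Of 22 CDK inhibitor and p53 target genes, Cdkn2a (1.28) and Cdkn2b (0.74) rose and Gadd45a (-1.58) fell in arrays labelled IKK2, also when adjusted over the list alone, and the set test gave an adjusted p of 0.939. Of 22 immediate early and heat shock genes, 5 fell and 3 rose (9 and 3 adjusted over the list alone), with Egr1 at -1.20 and Hspd1 at 0.96, and the set test gave an adjusted p of 0.0649. That list passed with the chip as a block (0.0279), with quantile normalization (0.0279) or 75th percentile scaling (0.0116) on the scanner scale, without S1 of Ctrl (0.0108) and without S1 or S2 of Myc (0.0459 each). The sets of cytokines, chemokines and receptors, of survival and apoptosis regulators, and of the unfolded protein response and secretion did not pass, with adjusted p-values of 0.216, 0.216 and 0.593.

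By limma, 1708 genes were called in IKK2 against Ctrl, 946 higher and 762 lower, and 117 changed at least 2-fold (39 higher, 78 lower). All 1708 moved the same way on both chips, which is again not replication, because the calls used these arrays. The chip as a block gave 2004 calls. The count was 877 and 886 without array S1 or S2 of Ctrl, 708 and 957 without array S1 or S2 of IKK2, and 619 without the 2 arrays of male pattern.

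**Figure D2:**
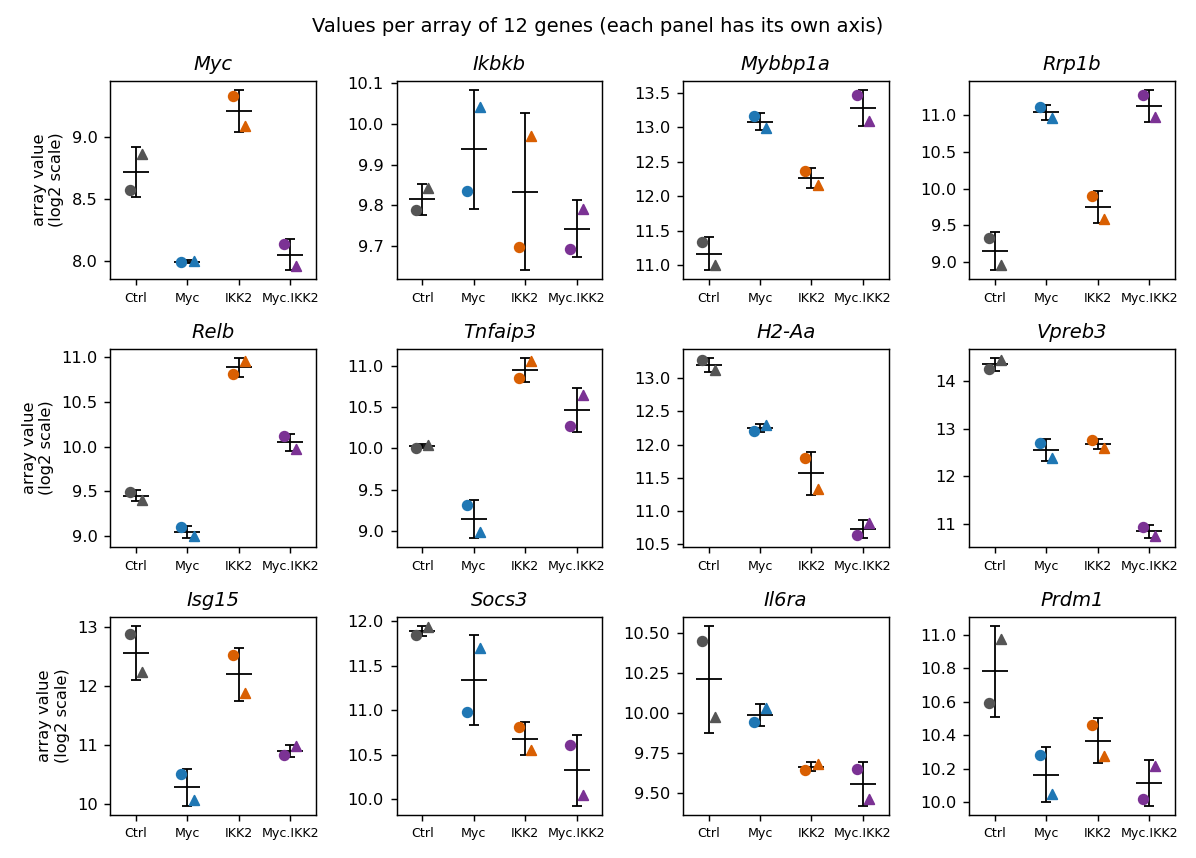
Array values (log2 scale, each panel with its own axis) of 12 genes in the 4 genotypes. Points are arrays (circle chip S1, triangle chip S2), the bar is the group mean and the whiskers are 1 SD of the n = 2 arrays; Relb rose by 1.44 in IKK2 against Ctrl, and H2-Aa and Vpreb3 fell by 2.47 and 3.51 in Myc.IKK2 against Ctrl.

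The Myc and IKK2 comparisons shared 1038 called genes, of which 608 were higher in both, 384 lower in both and 46 opposite. Independent lists of these sizes would share 104 genes higher and 68.8 lower. Among 50 simulations of unchanged groups with shared controls, at most 1 gene was called in both, but such groups hold almost no calls, so this does not measure sharing beyond the calls of each comparison. Across the 12447 genes, which are not independent replicates, the changes correlated at r = 0.597 against a simulated mean of 0.4996, with a covariance of 0.0599 against a simulated 0.00681. Part of the excess of shared calls over independent lists may come from the shared controls, which added little to the covariance in the simulations. With Myc taken on S1 and IKK2 on S2, or the reverse, each against the Ctrl array of its own chip, no Ctrl array was shared, and the covariance was 0.0514 and 0.0506 (r = 0.481 and 0.397), a comparison added after the data were seen.

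In arrays labelled Myc.IKK2, 31 of 33 ribosome biogenesis genes rose against Ctrl, and 25 of 33 mature B cell genes fell. C1qbp, a mitochondrial matrix protein, rose by 2.83 against Ctrl (SE 0.18, adjusted p = 1.44e-05), Serpina3f by 2.84 (SE 0.24, adjusted p = 5.41e-05), Dctd by 2.53 (SE 0.08) and Tfrc by 2.26 (SE 0.11, adjusted p = 6.9e-06). Vpreb3, which encodes a protein associated with the pre-B cell receptor, fell by 3.51 (SE 0.13, adjusted p = 3.84e-06), from 14.36 ± 0.14 (SD, n = 2) in Ctrl to 10.85 ± 0.14. The MHC class II gene H2-Aa fell by 2.47 (SE 0.15, adjusted p = 1.14e-05) and Apoe by 3.02 (SE 0.14). On chip S2 alone C1qbp changed by 2.63, Vpreb3 by -3.71 and H2-Aa by -2.30, and on chip S1 by 3.04, -3.31 and -2.64.

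The other large rises were Pip4p1 (2.60, with another bright probe at -0.51), Angptl4 (2.45), Tmem41a (2.42), Cd3eap (2.27), Ak7 (2.22) and Thop1 (2.21). The other large falls were Gpx3 (-3.05), Sgk1 (-3.02), Egr1 (-2.63), the IgM receptor gene Fcmr (-2.62), Egr3 (-2.53), Egr2 (-2.47) and the inhibitory receptor gene Lag3 (-2.45). Over the alternatives Pip4p1 ranged from 1.05 to 2.91, Angptl4 from 1.30 to 3.20 and Egr3 from -3.15 to -1.25.

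Of 33 ribosome biogenesis genes, 31 rose and none fell in arrays labelled Myc.IKK2 (32 and 0 adjusted over the list alone), with a median of 1.15 and within-chip medians of 1.16 and 1.12. Rrp9 (1.84), Nop2 (1.81) and the nucleolin gene Ncl (1.72) were among them. Camera gave an adjusted p of 4.79e-20, and 0.0459 with an estimated correlation. Of 26 genes of MYC-linked metabolism, 20 rose and 2 fell (21 and 3 adjusted over the list alone), with Shmt1 at 2.15 and the CTP synthase gene Ctps at 1.69. As a set it had an adjusted p of 1.26e-09, and 0.046 with an estimated correlation. Of 32 cell cycle genes, 13 rose and none fell (15 and 0 adjusted over the list alone), with Cdk4 at 1.13 and Tk1 at 0.99 (0.65 to 1.21 over the alternatives). For this list the adjusted p was 1.47e-05, and 0.223 with an estimated correlation.

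Of 33 mature B cell genes, 25 fell and none rose in arrays labelled Myc.IKK2 (26 and 0 adjusted over the list alone), with a median of -0.75 and within-chip medians of -0.73 and -0.72. H2-Ob (-2.36), H2-Ab1 (-1.93) and H2-Eb1 (-1.87) were among them. Its set test gave an adjusted p of 6.12e-15, and 0.0459 with an estimated correlation. Of 28 plasma cell genes, 17 fell and 5 rose (18 and 5 adjusted over the list alone), with Derl3, a gene of protein degradation from the endoplasmic reticulum, at -1.41, the elongation factor gene Ell2 at -1.03 and Fkbp11 at 0.67. The adjusted p was 0.000844, and 0.239 with an estimated correlation. Prdm1 changed by -0.66 (SE 0.14, adjusted p = 0.00751), a call that was lost without array S1 of Myc.IKK2 (-0.57) and without both arrays of male pattern (-0.57). Irf4 changed by -0.45 (SE 0.09, adjusted p = 0.00405), a call that was lost on the scanner scale with 75th percentile scaling (-0.31) or normexp (-0.32). Sdc1, which encodes CD138, changed by 0.34 (SE 0.11, adjusted p = 0.0475), and that call was lost in 12 alternatives, among them without 7 of the 8 single arrays (0.19 to 0.39, kept without S1 of Myc.IKK2). Xbp1 (-0.06) did not pass. Over the alternatives Ell2 ranged from -1.18 to -0.59, Prdm1 from -0.86 to -0.40 and Sdc1 from 0.19 to 0.49.

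Of 37 NF-kB target genes, 16 fell and 1 rose in arrays labelled Myc.IKK2 (18 and 4 adjusted over the list alone), with Nfkbiz at -1.95, Ccl5 at -1.71 and Traf1 at -1.01. Camera gave an adjusted p of 0.00476, and 0.243 with an estimated correlation. Of 23 IL6-JAK-STAT3 genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.27 and within-chip medians of -0.39 and -0.28. Socs3 changed by -1.57 (SE 0.24, adjusted p = 0.00116), Pim1 by -1.21, Il10 by -1.19 and Il6st, the signalling chain of the IL6 receptor, by -0.63 (SE 0.13, adjusted p = 0.00661). The list's adjusted p was 0.000329, and 0.046 with an estimated correlation. Il6ra, the binding chain, changed by -0.66 (SE 0.14, adjusted p = 0.00783), a call that was lost without array S2 of Myc.IKK2 (-0.56). Stat3 changed by -0.49 (adjusted p = 0.0259), a call that was lost without S1 (-0.53) or S2 (-0.46) of Ctrl and without S2 of Myc.IKK2 (-0.25), with 75th percentile scaling (-0.28) or normexp (-0.29) on the scanner scale, and with only these groups in the fit. Over the alternatives Pim1 ranged from -1.36 to -0.62, Il6ra from -0.89 to -0.42 and Stat3 from -0.77 to -0.21.

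Of 24 survival and apoptosis regulators, 14 fell and 3 rose in arrays labelled Myc.IKK2 (14 and 3 adjusted over the list alone). The survival receptor gene Tnfrsf13c changed by -1.22, the anti-death gene Bcl2l1 by -1.20 (-1.29 to -0.76 over the alternatives) and the pro-death gene Bcl2l11 by -1.20. As a set it had an adjusted p of 0.00101, and 0.134 with an estimated correlation. Of 25 interferon response genes, 15 fell and 1 rose (17 and 2 adjusted over the list alone), with Usp18 at -1.36 and Trim30a at -1.23. For this list the adjusted p was 3.23e-06, and 0.18 with an estimated correlation. Of 34 cytokine, chemokine and receptor genes, 15 fell and 1 rose (18 and 1 adjusted over the list alone), with Cxcr5 at -2.23 and the chemokine receptor gene Ccr6 at -2.00 (adjusted p = 5.44e-05, and 0.0459 with an estimated correlation). Of 37 genes of the unfolded protein response and secretion, 9 fell and 1 rose (9 and 1 adjusted over the list alone), with Ero1b at -1.49 (adjusted p = 0.000844, and 0.169 with an estimated correlation). Of 22 immediate early and heat shock genes, 14 fell and 5 rose (14 and 6 adjusted over the list alone), with Dusp1 at -2.04 and Hspd1 at 1.89 (adjusted p = 0.00316, and 0.239 with an estimated correlation). Of 22 CDK inhibitor and p53 target genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone), among them the CDK inhibitor gene Cdkn2a (1.46) and the stress gene Gadd45a (-2.03), and the set test gave an adjusted p of 0.694.

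By limma, 3868 genes were called in Myc.IKK2 against Ctrl, 2083 higher and 1785 lower (53.9% higher), and 576 changed at least 2-fold (318 higher, 258 lower). With 75th percentile scaling on the scanner scale 3871 genes were called, 62.4% of them higher. All 3868 moved the same way on both chips, which is not replication here either, because the calls used these arrays. The chip as a block gave 4224 calls. Without the 2 arrays of male pattern 2655 genes were called.

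**Figure D3:**
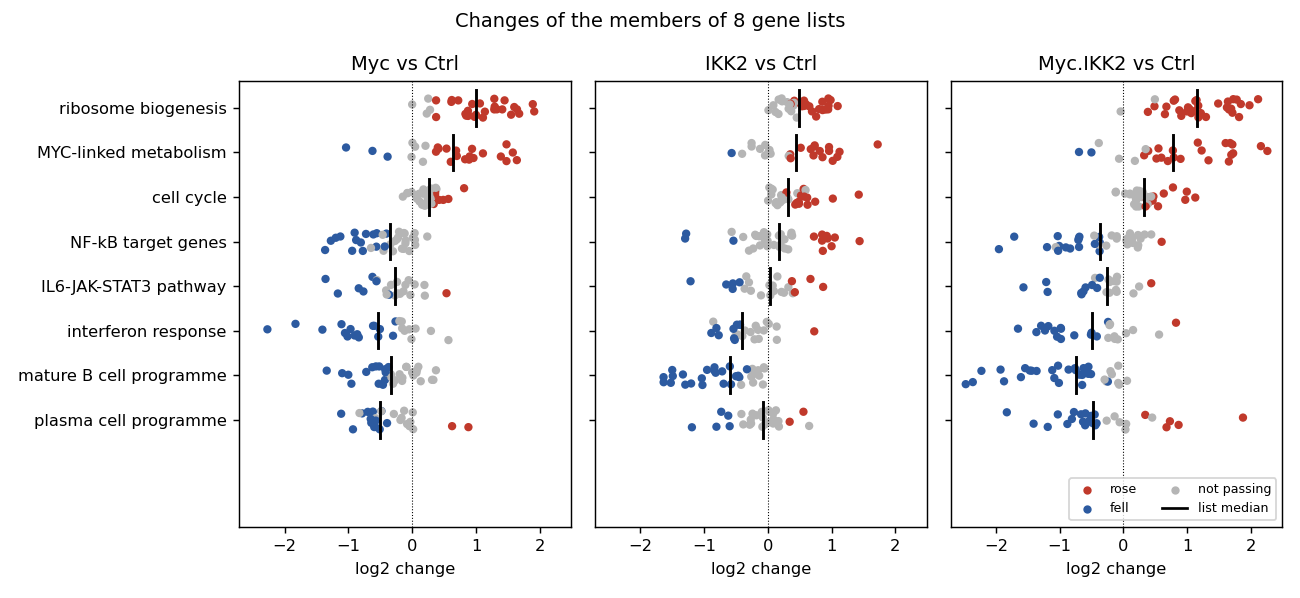
Log2 change (horizontal axis) of each tested member of 8 gene lists in Myc, IKK2 and Myc.IKK2 against Ctrl. Points are genes, coloured by whether they rose, fell or did not pass the test, and black bars are list medians; the ribosome biogenesis medians were 0.99, 0.50 and 1.15 and the mature B cell medians -0.32, -0.59 and -0.75.

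Set against arrays labelled Myc, those labelled Myc.IKK2 were higher in Serpina3f, by 4.07 (SE 0.24, adjusted p = 0.000263), in Ly6c1 by 1.79 (SE 0.21), in Tnfaip3, an inhibitor of NF-kB signalling, by 1.31 (SE 0.15, adjusted p = 0.00388), and in Set by 1.18 (SE 0.10). Slc39a4 was higher by 1.25 (SE 0.25, adjusted p = 0.0311), a call that was lost without array S2 of Myc (0.96) and without S1 (1.24) or S2 (1.25) of Myc.IKK2, and also with no filter and with sex as a covariate. The largest falls were Gadd45g (-1.74), Vpreb3 (-1.70), Apoe (-1.64), Fcmr (-1.58) and Gpx3 (-1.52). Of 37 NF-kB target genes, 5 rose and 2 fell (10 and 5 adjusted over the list alone), with Nfkbia, the main inhibitor of NF-kB, at 1.03 and Relb at 1.00, and the set test gave an adjusted p of 0.335 (0.0483 without S2 of Myc and 0.0491 without S1 of Myc.IKK2). Of 33 mature B cell genes, 14 fell and none rose (22 and 0 adjusted over the list alone), with H2-Ab1 at -1.50 (SE 0.08), H2-Eb1 at -1.45 and Cd22 at -1.32. The median was -0.45, with within-chip medians of -0.50 and -0.44, and the adjusted p was 3.77e-19, and 0.0843 with an estimated correlation. Of 26 genes of MYC-linked metabolism, 7 rose and none fell (8 and 0 adjusted over the list alone), with Psat1 at 0.71, a call lost without the 2 arrays of male pattern (adjusted p = 3.86e-06 for the list, and 0.21 with an estimated correlation). Of 22 CDK inhibitor and p53 target genes, 4 rose and 1 fell (8 and 2 adjusted over the list alone), with Cdkn2b at 0.86 (adjusted p = 0.03, and 0.235 with an estimated correlation), a list call that was lost without S1 or S2 of Ctrl (adjusted p = 0.0524 each) and with the stricter filter (adjusted p = 0.12). Ribosome biogenesis genes rose as a set, with a median of 0.21 and 2 called members, Nhp2 at 0.48 and Ncl at 0.43 (adjusted p = 0.000426, and 0.237 with an estimated correlation), but the call of Nhp2 was lost without any Myc, IKK2 or Myc.IKK2 array (0.39 to 0.57) and that of Ncl without any array except S1 of Myc (0.32 to 0.50). Some lists passed only in some of the alternatives: the cell cycle with 75th percentile scaling on the scanner scale (0.00185) and without S2 of Myc.IKK2 (0.00253), immediate early and heat shock genes without S1 of Myc (0.0239), and cytokines, chemokines and receptors in 5 alternatives, among them the stricter filter (0.0291) and fry (0.0401). Over the alternatives Set ranged from 0.61 to 1.36 and Cd22 from -1.74 to -0.76.

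By limma, 554 genes were called in Myc.IKK2 against Myc, 249 higher and 305 lower (44.9% higher), and 59 changed at least 2-fold. With 75th percentile scaling on the scanner scale 712 genes were called, 58.8% of them higher, and with normexp 544, 56.3% of them higher. The count was 278 and 138 without array S1 or S2 of Myc, 131 and 170 without S1 or S2 of Myc.IKK2, and 80 without the 2 arrays of male pattern. Sex as a covariate gave 219 calls, a fit of only these groups 322, and the chip as a block 765.

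Set against arrays labelled IKK2, those labelled Myc.IKK2 were higher in the glycolytic gene Pgam2 by 2.08 (SE 0.16, adjusted p = 0.000263), in the pyrimidine breakdown gene Upb1 by 1.85 (SE 0.12), in Angptl4 by 1.84 (SE 0.11), in Tmem41a by 1.80 and in Ryk by 1.78. Il4i1 fell by 2.34 (SE 0.18, adjusted p = 0.000291), Lag3 by 1.97 (SE 0.14), Hsd11b1 by 1.89, Vpreb3 by 1.83 and the phosphatase gene Dusp1 by 1.76. Of 37 NF-kB target genes, 17 fell and none rose (22 and 0 adjusted over the list alone), with Nfkbie at -1.31, Bcl2l1 at -1.15 and Relb at -0.84. The median was -0.51, with within-chip medians of -0.45 and -0.49, and the adjusted p was 2.9e-12, and 0.0491 with an estimated correlation. Of 23 IL6-JAK-STAT3 genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone), with Il10 at -1.51, Junb at -0.88 and Pim1 at -0.85 (adjusted p = 8.76e-06, and 0.037 with an estimated correlation). Of 33 ribosome biogenesis genes, 27 rose and none fell (30 and 0 adjusted over the list alone), with Rrp1b at 1.38 and Ncl at 1.15 (adjusted p = 1.41e-19, and 0.0338 with an estimated correlation). Over the alternatives Angptl4 ranged from 0.96 to 2.28, Junb from -0.98 to -0.46 and Pim1 from -0.98 to -0.44.

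Of 26 genes of MYC-linked metabolism, 14 rose and 2 fell in Myc.IKK2 against IKK2 (17 and 2 adjusted over the list alone), with Shmt1 at 1.06 (adjusted p = 4.37e-09, and 0.0491 with an estimated correlation). Of 34 cytokine, chemokine and receptor genes, 10 fell and none rose (15 and 0 adjusted over the list alone), with Cxcr5 at -1.39 and Il2ra at -1.33 (adjusted p = 1.01e-06, and 0.0338 with an estimated correlation). The survival and apoptosis regulators (7 of 24 fell, 0 rose), the unfolded protein response and secretion (6 of 37 fell, 0 rose), the plasma cell programme (8 of 28 fell, 3 rose), the mature B cell programme (10 of 33 fell, 1 rose), the interferon response (6 of 25 fell, 0 rose) and immediate early and heat shock genes (5 of 22 fell, 4 rose) were also lower as sets. Adjusted over the list alone, 12 fell and 2 rose, 7 and 0, 12 and 3, 10 and 2, 10 and 1, and 10 and 5. With an estimated correlation their adjusted p-values were 0.085, 0.085, 0.237, 0.2, 0.306 and 0.311, so none of these calls held. The last 4 of them were also lost without the 2 arrays of male pattern, which leaves 1 array per group. The medians were then -0.24, -0.12, -0.06 and -0.46, against -0.31, -0.11, -0.19 and -0.42 with all arrays. The last was also lost without S1 of Myc.IKK2 (adjusted p = 0.0563).

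By limma, 1668 genes were called in Myc.IKK2 against IKK2, 949 higher and 719 lower (56.9% higher), and 121 changed at least 2-fold. With 75th percentile scaling on the scanner scale 1791 genes were called, 71.2% of them higher, and with normexp 1546, 70.2% of them higher. The count was 1050 and 685 without array S1 or S2 of IKK2, 802 and 932 without S1 or S2 of Myc.IKK2, and 372 without the 2 arrays of male pattern, which leaves 1 array per group. Each group held 1 array of each pattern, and sex as a covariate gave 1760 calls. The chip as a block gave 2002 calls.

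The interaction asked whether the joint log2 change differed from the sum of the log2 changes of each genotype alone. Such a sum corresponds to a product of fold changes. Among the 318 genes that rose at least 2-fold in Myc.IKK2, the median joint change was 1.23 against a median sum of 1.53, and among the 258 that fell it was -1.23 against -1.44. The median difference per gene was -0.29 among the rises and 0.14 among the falls. The joint change was larger in size than the sum in 15.7% of the rises and 38.0% of the falls. These genes were chosen on the joint change, and both parts of the sum use the same Ctrl arrays. By limma 4 genes passed, each with an adjusted p of 0.0445. Ly6c1, a surface antigen gene, had an interaction of 2.52 (SE 0.29), Il4i1 of -2.22 (SE 0.26), Cavin3 of -1.36 (SE 0.14) and Atad3a of -1.16 (SE 0.13). Ly6c1 measured 13.12 ± 0.19 (SD, n = 2) in Ctrl, 12.19 ± 0.21 in Myc, 12.39 ± 0.28 in IKK2 and 13.99 ± 0.42 in Myc.IKK2. Cavin3 was not above the background level in Myc (7.90) or Myc.IKK2 (7.92), so its change between them was not measured and the size of its interaction is uncertain. With the chip as a block, which pairs the genotypes, 4 genes were called: Il4i1, Cavin3 and Atad3a were kept, Ly6c1 was lost (adjusted p = 0.0759, with 1.02e-06 to 0.204 over the alternatives) and Sgk1 was gained. At an unadjusted p under 0.05, 1415 genes passed. Each of the 4 calls was lost without most single arrays: 7 genes were called without S1 of Ctrl (Cavin3 and 6 others), 1 without S2 of Myc.IKK2 (Il4i1), and 0 by limma without any other array, where 966 to 1520 genes had an unadjusted p under 0.05.

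As sets, ribosome biogenesis genes had a median interaction of -0.33 (within-chip medians -0.33 and -0.41), cell cycle genes of -0.30 (-0.11 and -0.33), MYC-linked metabolism genes of -0.16 (-0.14 and -0.19), interferon response genes of 0.27 (0.30 and 0.26) and CDK inhibitor and p53 target genes of 0.15 (0.31 and 0.10). Their adjusted p-values were 8.26e-10, 1.76e-07, 0.006, 1.76e-07 and 0.006, and with an estimated correlation the adjusted p-values were 0.193, 0.315, 0.315, 0.315 and 0.223. With 75th percentile scaling on the scanner scale the median of MYC-linked metabolism was -0.08 and its call was lost (adjusted p = 0.21). With fry the calls of MYC-linked metabolism, cell cycle and the interferon response were lost (adjusted p = 0.0568, 0.0987 and 0.0749). No member of these lists passed over all genes by limma, and adjusted over the list alone 0 rose and 12 fell, 0 and 2, 4 and 8, 6 and 0, and 3 and 1. The plasma and mature B cell lists passed only in some alternatives, both without S1 of Myc.IKK2 (0.00455 and 0.0091) and without the 2 arrays of male pattern (0.00582 each). Over all comparisons 50 list calls were made, and 13 held with an estimated correlation and 46 with fry.

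Few markers of other cell types passed the test, though the largest of their changes were not small. Lyz1 and Lyz2, of myeloid cells, differed by 1.18 (SE 0.66, adjusted p = 0.231) and 0.97 (SE 0.36, adjusted p = 0.0702) in Myc.IKK2 against Ctrl, and the T cell gene Cd3g by 0.998 (SE 0.34, adjusted p = 0.0766) in Myc against Ctrl, without passing. Of 10 T cell, 12 myeloid and dendritic cell and 7 erythroid and platelet markers tested, limma called 0 in each comparison with Ctrl, also when adjusted over the list alone except for 1 rise and 1 fall of the erythroid and platelet list in IKK2 (Car2 and Hbb-bt). Of 5 NK cell markers, Prf1 rose in Myc (0.75, SE 0.22, adjusted p = 0.0444), a call that was lost without any single array except S1 of Ctrl (0.34 to 0.87). Camera gave these lists adjusted p-values from 0.262 to 0.967 against Ctrl, whereas fry gave 0.0108 for a rise of the NK cell list in Myc and 0.0249 for a fall of the T cell list in Myc.IKK2 (0.0401 against Myc and 0.025 against IKK2). In Myc.IKK2 against IKK2 the T cell marker Cd8b1 fell by 0.39 by limma (adjusted p = 0.014). This call was lost without S1 (-0.40) or S2 (-0.37) of IKK2 or S2 of Myc.IKK2 (-0.34). It was also lost on each scanner scale, with the mean of all probes and without the 2 arrays of male pattern. Another bright probe of that gene changed by 0.04.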

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

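Values that differed between genotypes beyond the sum of the changes of each genotype alone were collected, and the tests of ribosome biogenesis were set before the result was seen, while the tests of the sex pattern and of the Myc probe were chosen after it was seen. By limma 4 genes had an interaction of the Myc and IKK2 genotypes: Ly6c1 (2.521), Il4i1 (-2.220), Cavin3 (-1.361) and Atad3a (-1.164). Cavin3 was not above background in Myc or Myc.IKK2, so the floor of the scale can produce its value, and the Ly6c1 call was lost with the chip as a block (adjusted p = 0.0759). List medians of the interaction were -0.332 for ribosome biogenesis, -0.156 for MYC-linked metabolism, -0.298 for cell cycle, 0.154 for CDK inhibitors and p53 targets and 0.269 for the interferon response. With an estimated correlation each of these list calls was lost (adjusted p = 0.193, 0.315, 0.315, 0.223 and 0.315). For CDK inhibitors and p53 targets the estimate was -0.015, below the preset 0.01, yet the unadjusted camera p went from 0.00176 to 0.0263. That loss therefore cannot be laid to correlation between the members.

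As a set, ribosome biogenesis genes rose less in Myc.IKK2 than the sum of the changes in Myc and in IKK2, but the call was lost with an estimated correlation (adjusted p = 0.193) and 0 of 33 members passed over all genes by limma. The compressed scale of the authors' table did not account for it. The median interaction was -0.316 on the scanner scale with 75th percentile scaling (-0.3815 relative to all genes). That scale keeps the authors' order of probes within each file and again sets arrays to equal levels. It therefore cannot exclude the rest of their processing or a shift of whole arrays. The upper end of the intensity scale did not account for the pattern. The 24 members with a Myc.IKK2 mean under 13 had a median of -0.3297 (quartiles -0.519 and -0.0449). A single Ctrl array did not account for it either, with -0.2975 and -0.3856 without each. The sum was of log2 changes, and whether the pattern holds for a sum on the scale of intensities was not tested. Differences between cultures or animals were not tested either, and no further cause was tested.

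The sex pattern of the IKK2 and Myc.IKK2 arrays of chip S1 was examined for IKK2 against Ctrl only, with a test chosen after the pattern was seen. Changes in Myc.IKK2 were not tested in this way. With sex as a covariate, limma called 219 genes in Myc.IKK2 against Myc, compared with 554 without it. Of the 554, 0 changed sign. Within IKK2 and Myc.IKK2 the male pattern was on S1 only, so sex cannot be told apart from chip there. No Myc array had the male pattern, so the covariate also makes this comparison less precise. The lower count thus does not show how many calls were due to sex. The test for IKK2 against Ctrl took the 149 genes outside the sex-linked list with an IKK2 difference of at least 1 log2 on chip S1. On S2 both arrays had the female pattern. The median ratio of the difference on S2 to that on S1 was 0.8663 (quartiles 0.6285 and 1.0997), and 97.32% had the same sign. Sex as the source of those changes was thus not borne out, though genes were chosen on S1 and the ratio is drawn towards lower values by that choice.

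The Myc probe was lower in both genotypes labelled as carrying Myc, and all tests of this were chosen after it was seen. A swap of the Myc and Ctrl labels was not borne out, because ribosome biogenesis genes had a median change of 0.9938 (quartiles 0.7226 and 1.3281) in Myc against Ctrl, which rests on the known link of MYC to these genes. A probe outside the transcript of the added allele could not be told apart from this data (-0.7193 in Myc against Ctrl). A lower transcript from the cell's own Myc gene cannot be told apart either, because its test, the change of -1.1528 in Myc.IKK2 against IKK2, only restates the pattern, with the probe near background in Myc.IKK2.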

How the results depend on the processing

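Alternatives marked here as added (the scanner scale, sex as a covariate, and the fit without the 2 arrays of male pattern) were chosen after seeing the data, and the cause of the moves was not tested. No named call reversed in sign. Over all called genes, the mean of all probes changed the sign of 7 in Myc against Ctrl, 7 in Myc.IKK2 against Ctrl and 2 in Myc.IKK2 against IKK2 (Ctse and Yipf2, of which Ctse was then called higher), and no other alternative changed any. Myc against Ctrl (2495 genes) gave 4138 with the 16 files as separate samples and 1415 to 2432 without single arrays. IKK2 against Ctrl (1708) gave 3400 with 16 files, 708 to 1608 without single arrays and 619 without the male-pattern arrays. Myc.IKK2 against Myc (554) gave 2450 with 16 files, 1462 with the array as a random block, 322 with only the groups compared, 131 to 485 without single arrays, 219 with sex as a covariate and 80 without the male-pattern arrays. Myc.IKK2 against IKK2 (1668) gave 3407 with 16 files, 685 to 1609 without single arrays and 372 without the male-pattern arrays, which leaves 1 array per group, while sex as a covariate gave 1760. The interaction (4) gave 10 on the scanner scale with quantile normalization, 8 with the stricter filter, 920 with 16 files, 316 with the random block, 2 with the mean of all probes, 11 with trend and robust settings, and 0 to 7 without single arrays. It gave 0 by limma with no filter (1727 at an unadjusted p under 0.05) and 0 without the male-pattern arrays (1310). A lone array left in a group was assumed to vary like the other groups.

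The chip as a replicate block gave 2827, 2004 and 4224 calls in Myc, IKK2 and Myc.IKK2 against Ctrl, 765 in Myc.IKK2 against Myc, 2002 against IKK2 and 4 in the interaction. Of these 4, Il4i1, Cavin3 and Atad3a were shared with the model without the block, Ly6c1 was lost and Sgk1 was gained. The differences between chips correlated between genotypes at r = 0.05 to 0.34, so the labels S1 and S2 may mark more than the position of arrays. Of 322 named calls, 239 were kept under all alternatives. The size of 68 of the 322 moved by more than 1.5 times in at least 1 alternative or within a chip, 45 of them with the mean of all probes.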

Other observations

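Serpina3f, a protease inhibitor gene, measured 10.43 in Ctrl, 9.198 in Myc, 13.40 in IKK2 and 13.27 in Myc.IKK2. It was higher with the IKK2 label whether or not Myc was present. Relb did the same, by 1.44 in IKK2 against Ctrl and by 1.00 in Myc.IKK2 against Myc, though it was also lower by 0.84 in Myc.IKK2 than in IKK2.

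A hypothesis is that added MYC lowers part of the NF-kB target genes, with or without added IKK2. Their median change was -0.34 in Myc against Ctrl and -0.51 in Myc.IKK2 against IKK2. Camera with an estimated correlation gave adjusted p-values of 0.0794 and 0.0491. The fall was not particular to this list. The interferon response (-0.53 and -0.19), plasma cell (-0.50 and -0.31) and IL6-JAK-STAT3 (-0.27 and -0.36) medians also fell, while ribosome biogenesis (0.99 and 0.65) and MYC-linked metabolism (0.65 and 0.51) rose. All arrays had about the same median, so these changes are relative to other genes. The median interaction of the NF-kB target genes was -0.06 and did not pass by camera (adjusted p = 0.313, and 0.808 with an estimated correlation). The change with IKK2 was thus not shown to depend on Myc. The hypothesis could be tested by protein and phosphorylation measurements of the pathway in cells of each genotype from several animals. More animals are needed because leaving out single arrays gave 685 to 1609 calls in Myc.IKK2 against IKK2. Whether the added alleles are read by the probes could be tested with the allele sequences, since the Myc probe changed by -1.1528 in that comparison.

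Il6 lay at the background level on all arrays and Il6st fell by 0.63 in Myc.IKK2 against Ctrl. Dependence on IL6 was not measured by these arrays, and a test would compare growth of the genotypes with and without the cytokine.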
